A study of Citrullus lanatus with 30 samples.

How the data were processed

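Total RNA from whole roots of watermelon (Citrullus lanatus) seedlings was hybridised to 30 one-colour Agilent oligonucleotide arrays, 1 sample per array. Roots had been dipped for 15 min in a conidial suspension of Fusarium oxysporum f. sp. niveum (FON), the fungus that causes Fusarium wilt of watermelon, or in water (mock), and were collected at 5 times, 12 h and 1, 3, 5 and 8 days later. Each of the 10 groups held 3 arrays, taken from the sample titles, and no sample was left without a group. The series' design text speaks of independent experiments, but the labels do not say that a replicate number marks an experiment, so arrays were not paired. The protocol field of the labels describes an RNA kit for blood, which does not match a root sample, so the extraction is not known here.

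The scanner files were written by Agilent Feature Extraction, version 10.5.1.1 per the file headers and version 9.1 per the submitters' processing notes. Each file held 15250 spots, of which 536 were controls and 14714 were probes with 1 spot each. The deposited intensity called the processed signal here is, per the file headers, a spot's Cy3 brightness after background subtraction and spatial correction by the software. On 10 of the 30 arrays the file headers also record a multiplicative correction, and there the processed signal differs from the background-subtracted one by a smooth surface over the array. On the other 20 arrays this step left the signal as it was, and the highest SD of log2 processed over background-subtracted signal was 1.98e-06 among probes well above background on every array. The background-subtracted signal, the deposited intensity before that multiplicative step, is in the same files. The deposited value table of the series held the processed signal itself, with a largest difference of 2.46e-06 on the log2 scale, so its scale is linear, without centring.

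The main values were log2 processed signals minus each array's 75th percentile. Spots with an outlier flag, 1081 in all or 0.245% of values, were left out, and no probe was saturated. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which kept 13973 probes and left out 741. Between 90.5% and 96.3% of probes per array were well above background, and the 75th percentile of the processed signal ran from 16858 to 23473. The number of arrays limits the precision.

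All 30 arrays entered 1 limma model (limma 3.58.1 in R 4.3.3) with a mean per group, so that every comparison shared 1 estimate of the spread. Inoculated minus mock was tested at each time and as the mean over the 5 times with limma's moderated test, and F tests addressed a response at any time, a response that differs between times and a change over time in mock roots. P-values were adjusted by the Benjamini-Hochberg method and a probe was called at an adjusted p under 0.05. Called probes shared between times were set against the number 2 independent lists would share, with Fisher's exact test, two-sided.

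The files used here do not pair the probe identifiers with gene names, so the gene lists and cell type markers fixed beforehand could not be applied. By the rule fixed for that case, up to 2 probes that were higher and 2 that were lower are named per comparison. They are the called probes whose 3 inoculated arrays all lay above or all below the 3 mock arrays and whose difference was largest, or, for the mean over times, those with the smallest p. Where a probe was not well above background on any array of a group, the fold is a lower bound, computed from the brighter group's mean against, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

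The arrays lay on 4 slides with 2 rows of arrays each, and each slide was 1 scan. The alternatives fixed before the data were examined were centring on the median, quantile normalization, normexp background correction with an offset of 50, the authors' value table, no filter or a stricter filter on dim probes, the slide as a fixed or random block, each time on its own, a replicate block, an intensity trend with robust variance, array weights, a 2-fold minimum and leaving out each array in turn. Normexp was planned on mean spot signals and was run on the median spot signals. Chosen after the data were examined were the background-subtracted signal (scaled to the 75th percentile, floored at 10, then log2), the array row as a block, subsets of arrays, and the averaging of probes linked by their numbers. Because the multiplicative correction entered the main values on 10 arrays, results from that signal are printed beside the main ones, although array weights moved several counts further.

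The model was tested on simulated data made from the real means and spreads of 13973 probes, with known changes. For the inoculation effect at 3 days, 55.2% of 67 probes changed by 1 log2 unit and 98.5% of 66 probes changed by 2 units were recovered with the spread of the processed signal. With the spread of the background-subtracted signal, 95.5% and 98.5% were recovered, and 3.67% of calls were false. When the software's real surfaces were added to those simulated values, 58.2% of the probes changed by 1 unit were recovered. Of the calls at 3 days 33%, 112 probes, were then false. Shares of false calls depend on how many probes were changed in the simulation, so they do not carry over to the real calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.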

Results

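Transcript levels were measured in whole watermelon roots at 12 h and at 1, 3, 5 and 8 days after inoculation with FON, and in water-dipped mock roots at the same times, with 3 arrays per group and 30 arrays in all. The design sets inoculated against mock roots at each time, and by its title the series addresses the transcriptional course of an incompatible interaction, one in which the plant resists the fungus. Between 90.5% and 96.3% of the 14714 probes were well above background on each array. No pair of arrays held identical values. The design text speaks of independent experiments without tying arrays to them, so p-values measure only the spread between these samples, which may be technical. Levels are log2 processed signals relative to the array's 75th percentile, given as mean ± SD with n = 3, and adjusted p-values are from limma. The software's multiplicative correction on 10 arrays added a surface to the processed signal, with an SD of 0.17 to 1.01 on the log2 scale, so counts from the background-subtracted signal stand beside the main counts.

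**Figure D1:**
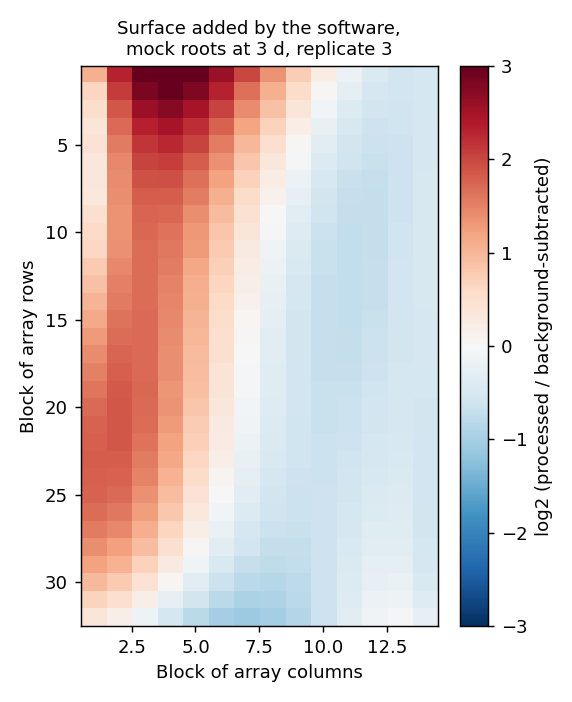
Mean log2 ratio of processed to background-subtracted signal over blocks of array columns (x axis) and array rows (y axis) on the third array of mock roots at 3 days, with colour giving the ratio. The ratio changes smoothly along both axes. It goes from 3.32 at row block 1 and column block 4 to -0.52 at row block 32 of that column block. Along row block 1 it falls to -0.54 at column block 14. The 99th percentile over probes is 2.89 and the SD is 1.01.

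At 12 h the differences between inoculated and mock roots were the smallest of the 5 times. Over all probes their SD on the log2 scale was 0.32, and 0.30 in the background-subtracted signal. At 1 day these were 0.46 and 0.45. The number of calls is a poorer measure of size. All times shared 1 estimate of the spread, so arrays of other times also affected how many probes passed at each time. The largest fall was that of xigua10499, which was 5.11-fold lower in inoculated than in mock roots (-4.21 ± 0.22 against -1.86 ± 1.32, adjusted p = 0.0173). The probe xigua03927 was 5.06-fold lower (-4.22 ± 0.22 against -1.88 ± 1.28, adjusted p = 0.017). Under the alternatives their log2 differences ran from -3.15 to -1.49 and from -3.08 to -1.50. The probes xigua08652 and xigua08919 were higher, by 2.55-fold (adjusted p = 0.0394) and 2.46-fold (adjusted p = 0.0368). In all, 20 of 13970 probes were called, 6 higher and 14 lower in inoculated roots, and 1045 had an unadjusted p under 0.05. The background-subtracted signal called 2180 probes, 911 higher and 1269 lower (1574 and 735 when centred on the median). Among the 2180 were all 20 of the main calls in the same direction, and 96 of the 2180 differed at least 2-fold. Inoculated arrays and mock replicate 1 lay in array row 1, and mock replicates 2 and 3 in row 2, so row partly follows inoculation. With limma, 0 probes were called with the array row as a block (675 at an unadjusted p under 0.05), and 47 with the slide as a block. Centring on the median gave 13 higher and 13 lower, the replicate block 0 and 6, and array weights called 6983 probes. Without inoculated replicates 1, 2 and 3 and mock replicates 1 and 2 the calls were 6, 6, 2, 8 and 0, with 617 at an unadjusted p under 0.05 in the last case. Each of the 4 named probes lost its call without any 1 of at least 5 of the 6 arrays, with adjusted p-values up to 0.332.

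At 1 day, xigua02709 and xigua09281 were higher in inoculated roots and not well above background on any mock array. They were at least 8.21-fold and at least 7.35-fold higher (adjusted p = 0.0114 for each), with inoculated levels of -7.10 ± 1.52 and -7.26 ± 1.42. These bounds hold for the processed signal, and under the alternatives the log2 differences ran from 1.67 to 5.53 and from 1.38 to 4.76, with the lowest from normexp. At 12 h xigua02709 was well above background on 2 of the 3 inoculated arrays and on 0 mock arrays, a difference that did not pass the test (adjusted p = 0.459). The probe xigua12299 was 9.55-fold lower in inoculated roots (-9.88 ± 1.15 against -6.62 ± 0.40, adjusted p = 0.000129) and xigua05727 was 7.87-fold lower (adjusted p = 0.000274), although they were well above background on only 2 and 1 of the 3 inoculated arrays, and under the alternatives their log2 differences ran from -3.83 to -1.42 and from -3.50 to -1.12. Both were called in the opposite direction at 3 days, when xigua12299 was 3.17-fold higher (adjusted p = 0.00897) and xigua05727 was 2.35-fold higher (adjusted p = 0.045), and both were lower again at 5 and 8 days, by 4.79-fold and 7.08-fold for xigua12299. In all, 668 probes were called, 357 higher and 311 lower, 444 of them with at least a 2-fold difference. From the background-subtracted signal 6038 were called, 1960 higher and 4078 lower (2806 and 2315 when centred on the median). These 6038 included 666 of the 668 in the same direction, and 594 of them differed at least 2-fold. Inoculated replicates 1 and 2 lay on slide 1 in array row 2, and replicate 3 and the mock arrays on slide 2 in row 1. Slide and row thus partly follow inoculation at this time. Centring on the median turned the split to 524 higher and 242 lower. The slide as a block left 151 calls (547 with the array row), none of the 4 named probes among them. Leaving out any 1 of the 6 arrays gave 235 to 431. Fitted on its own, this time gave 4293 calls, 1672 higher and 2621 lower. The call of xigua02709 was lost without inoculated replicate 1 or 3 or mock replicate 1 or 2 (adjusted p up to 0.0797), and that of xigua09281 without inoculated replicate 1 or mock replicate 1 or 2 (up to 0.0854).

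At 3 days the probes xigua12247 and xigua05675 were 7.37-fold and 6.96-fold higher in inoculated roots (adjusted p = 6.09e-07 and 7.38e-07). Their levels were -1.73 ± 0.81 and -1.92 ± 0.76 against -4.61 ± 0.40 and -4.72 ± 0.30 in mock roots, and their log2 differences ran from 2.20 to 3.23 and from 2.28 to 3.12 under the alternatives. The probe xigua08039 was 13.1-fold lower (-1.58 ± 0.53 against 2.14 ± 1.00, adjusted p = 5.2e-07) and 8.38-fold lower in the background-subtracted signal. It was also 8.51-fold lower at 5 days (adjusted p = 4.65e-06) and had no called difference at 8 days (1.44-fold, adjusted p = 0.447). The probe xigua00958 was not well above background on any inoculated array and was at least 4.4-fold lower than in mock roots in the processed signal (adjusted p = 8.8e-07, log2 differences from -3.97 to -0.85 under the alternatives). In all, 2864 probes were called, 1600 higher and 1264 lower, and 1176 differed at least 2-fold. The background-subtracted signal called 6121, 3334 higher and 2787 lower (2141 and 3643 when centred on the median). Of the 6121, 2077 were shared with the main calls in direction, and 922 differed at least 2-fold. Mock replicates 2 and 3 carried the 2 largest surfaces of the software, with an SD of 0.79 and 1.01, and no inoculated array of this time carried one. These mock arrays lay on slide 3 in array row 1, and mock replicate 1 and the inoculated arrays on slide 2 in row 2. Surface, slide and row thus partly follow inoculation at this time. The 3 mock arrays lay on 2 slides, and 451 probes were called with the slide as a block, 1162 with the array row as a block and 1395 on the arrays of 1 slide and row, where a single mock array stood against 3 inoculated arrays and was assumed to vary like the other groups. Fitted on its own, this time gave 177 calls, 28 higher and 149 lower, and 2910 in the background-subtracted signal. Centring on the median gave 900 higher and 1988 lower and moved the median of all probes from 0.02 to -0.14, and the count was 1728 and 1794 without inoculated replicates 2 and 3, and 4761 and 4414 without mock replicates 1 and 2.

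At 5 days the named probes, chosen for their large differences, differed by more than those named at other times. Over all probes the differences were not largest at 5 days. Their SD on the log2 scale was 0.61, against 0.64 at 3 days and 0.64 at 8 days. In the background-subtracted signal it was 0.56 at 5 days, 0.55 at 3 days and 0.63 at 8 days. The probe xigua07711 was 97.8-fold higher in inoculated roots (0.02 ± 1.37 against -6.59 ± 0.85, adjusted p = 2.87e-10). Its mock level had been 2.38 ± 0.27 at 12 h and was -8.41 ± 0.52 at 8 days, and its inoculated level went from 2.55 ± 0.50 to -3.26 ± 0.06 over the same interval. The probe xigua14511 was 98.1-fold higher (adjusted p = 2.87e-10), with only 1 of 3 mock arrays well above background. Under the alternatives the log2 differences of xigua07711 and xigua14511 ran from 5.53 to 7.33 and from 5.09 to 7.34. The probes xigua12204 and xigua05632 were not well above background on any inoculated array and were at least 16.9-fold and at least 15.1-fold lower than in mock roots (adjusted p = 9.17e-06 and 1.32e-06), where they stood at -5.40 ± 0.16 and -5.33 ± 0.16. These bounds too hold for the processed signal, and the log2 differences ran from -6.20 to -2.56 and from -5.61 to -2.69 under the alternatives. In all, 1674 probes were called, 702 higher and 972 lower, and 1021 differed at least 2-fold. From the background-subtracted signal 5523 were called, 2594 higher and 2929 lower (2965 and 2619 when centred on the median), including 1631 of the main calls in the same direction, and 962 differed at least 2-fold. All 6 arrays shared a slide, but inoculated replicates 1 and 2 lay in array row 1, and replicate 3 and the mock arrays in row 2. Row thus partly follows inoculation here as well. Inoculated replicate 1 also carried a surface with an SD of 0.72. The array row as a block left 1189 calls and a fit of this time on its own 1037. Without inoculated replicate 1 and mock replicates 1 and 2 the calls were 1022, 1070 and 1083.

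At 8 days xigua14159 and xigua07842 were 69.9-fold and 68.4-fold higher in inoculated roots (adjusted p = 9.27e-12 and 5.69e-11). The level of xigua14159 was 0.81 ± 0.29 against -5.32 ± 0.66 in mock roots, where it had been 2.16 ± 0.50 at 3 days and -1.49 ± 0.10 at 5 days, and the difference was already 8.95-fold at 5 days (adjusted p = 1.89e-06). The probes xigua13698 and xigua07126 were 14.4-fold and 13.4-fold lower (adjusted p = 2.44e-08 and 1.1e-10), and they had been 6.75-fold and 6.06-fold lower at 5 days (adjusted p = 7.55e-06 and 2.08e-07). In all, 1826 probes were called, 1097 higher and 729 lower, and 981 differed at least 2-fold. The background-subtracted signal called 7458, 4216 higher and 3242 lower (3492 and 3969 when centred on the median), including 1825 of the main calls in the same direction, and 1063 differed at least 2-fold. All 6 arrays shared a slide, but inoculated arrays lay in row 1 and mock arrays in row 2, so that array row and inoculation cannot be told apart within this time, and 1146 probes were called with the row as a block estimated over all times. Fitted on its own, this time gave 3106 calls. The count was 1159, 1190 and 1072 without inoculated replicate 1 and mock replicates 1 and 2.

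**Figure D2:**
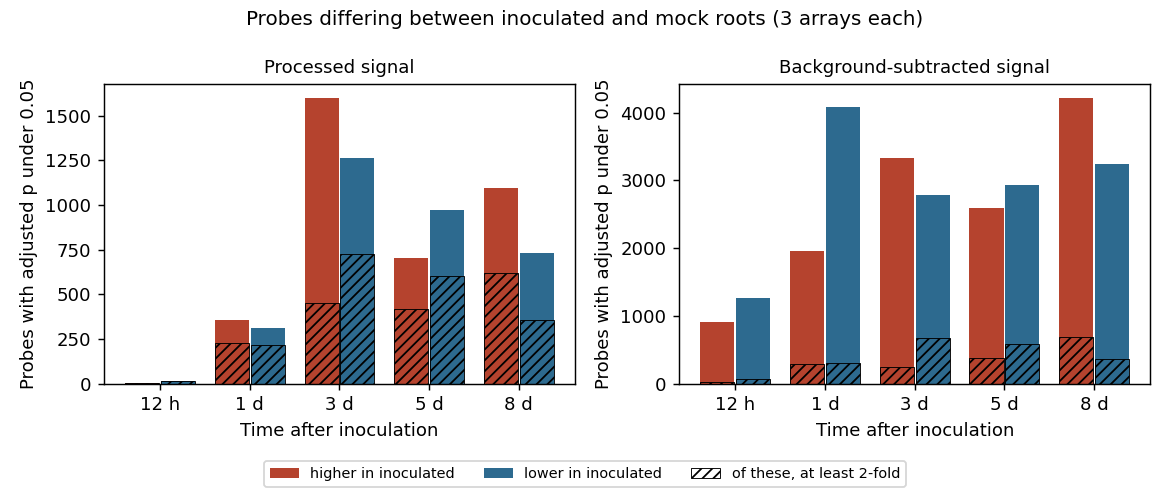
Probes called at an adjusted p under 0.05 in inoculated against mock roots (y axis, number of probes) at each time (x axis), from the processed signal (left) and the background-subtracted signal (right, on its own scale), with hatching for those that differ at least 2-fold. The processed signal gives 20 calls at 12 h and 2864 at 3 days, and the background-subtracted signal 2180 and 6121.

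**Figure D3:**
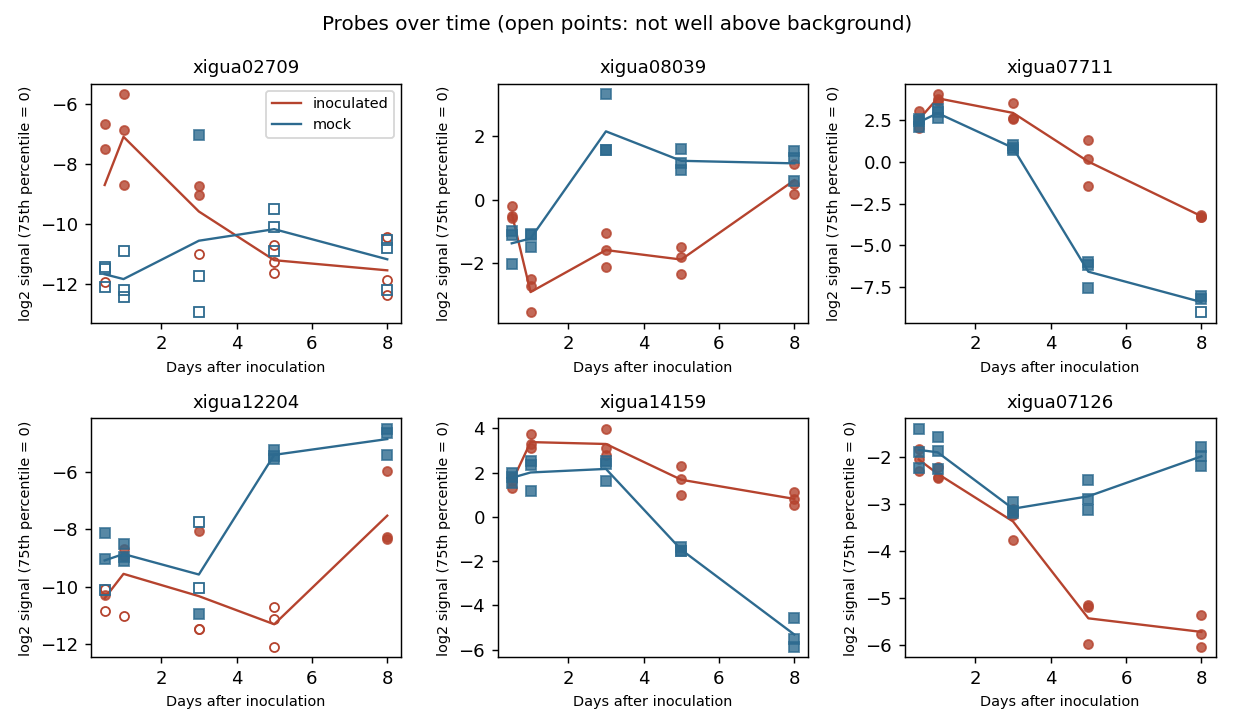
Level of 6 named probes (y axis, log2 signal with the array's 75th percentile at 0) against days after inoculation (x axis), with a point per array (red inoculated, blue mock, open where not well above background) and lines through the means of 3 arrays. Signals of xigua07711 and xigua14159 fell in mock roots between 3 and 5 days and lay higher in inoculated roots at 5 and 8 days, with a smaller gap at 1 and 3 days, and xigua12204 was near background in inoculated roots at 5 days.

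Over the 5 times, the mean difference was positive for xigua14511 (3.03 on the log2 scale, SE 0.20, adjusted p = 1.42e-10) and xigua07711 (2.98, SE 0.20, adjusted p = 1.42e-10). For xigua14511 this mean is not exact, since at 8 days the probe was not well above background on any mock array and only a difference of at least 9.19-fold is known. The mean difference was negative for xigua07126 (-1.46, SE 0.11, adjusted p = 1.44e-09) and xigua01167 (-1.42, SE 0.12, adjusted p = 3.91e-09). The probe xigua01167 was lower at 12 h and 1, 5 and 8 days, by 2.8-fold, 4.97-fold, 4.6-fold and 2.44-fold, and did not differ by the test at 3 days (adjusted p = 0.659). The mean effect was called for 2174 probes, 1012 higher and 1162 lower, and a response at any time for 4227. The background-subtracted signal called 6730 and 11672. Without mock replicate 2 at 3 days the mean effect was called for 3465 probes.

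The response differed between times for 3292 probes (F test), among them xigua07711 (adjusted p = 9.39e-08), xigua14159 (4.6e-08), xigua08039 (3.56e-06) and xigua02709 (0.0328). The probe xigua08652 was 2.55-fold higher at 12 h, then 5.58-fold lower at 3 days (adjusted p = 1.08e-06, and 8.45-fold lower in the background-subtracted signal), and its response also differed (adjusted p = 1.37e-07). Between neighbouring times the response changed for 56 probes from 12 h to 1 day, 1591 from 1 to 3 days, 1308 from 3 to 5 days and 713 from 5 to 8 days. In the background-subtracted signal the response differed for 10998 probes, and 2648, 6441, 5116 and 5457 between neighbouring times. With the slide as a block 2009 probes were called, and 5106, 5059 and 5002 were called without mock replicates 1, 2 and 3 at 3 days.

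Called probes were shared most between 5 and 8 days, when 537 were called in the same direction and 72 in opposite directions, against 105.8 and 112.9 for independent lists. The probes xigua13698 and xigua07126, which may measure 1 target (last paragraph), were among those lower at both times. Between 3 and 5 days 495 were shared in direction and 94 opposed, against 168.3 and 174.8. At 12 h and 3 days 0 calls agreed and 12 opposed, against 1.95 and 2.15, and in the background-subtracted signal 210 agreed and 1013 opposed, against 470.5 and 484.5. At 12 h the inoculated arrays lay in array row 1 and mock replicates 2 and 3 in row 2, and at 3 days this was reversed. At 5 and 8 days most inoculated arrays lay in row 1 and all mock arrays in row 2. A difference between array rows could therefore enter both the opposed and the shared calls. Fisher's exact tests of the higher calls at 5 and 8 days gave a two-sided p of 1.63e-154 before adjustment over 10 pairs of times. Probes are not independent replicates. In all, 1251 probes were called in the same direction at 2 or more times, 1124 of them with no opposite call at another time, and 416 probes were called in both directions. In the background-subtracted signal these were 6957, 3944 and 4789.

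In mock roots 7062 probes changed over the 5 times (F test), and 12199 in the background-subtracted signal. The signals of xigua07711 and xigua14511 fell over time (adjusted p = 2.65e-17 and 2.81e-17), and so did that of xigua14159 (adjusted p = 1.18e-14), while xigua12204 rose from -9.08 ± 0.99 at 12 h to -4.85 ± 0.50 at 8 days (adjusted p = 1.25e-05). Among called probes 1294 were at least 2-fold higher and 989 at least 2-fold lower at 8 days than at 12 h. Mock arrays of 12 h, 1, 5 and 8 days lay on slides 1, 2, 3 and 4, and slide 4 held no other time, so that for 8 days slide and time cannot be told apart, and the comparison of 8 days with 12 h sets slide 4 against slide 1. With the slide as a block, which leaves 8 days uncorrected, 5815 probes were called. The replicate block gave 2269, but in that fit the test compared levels at replicate number 1 instead of group means.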

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

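The tests of the change between neighbouring times and of the interaction were fixed before the data were examined, and the counts from the background-subtracted signal were added afterwards. The response to inoculation differed between times by an F test for 3292 probes in the processed signal and 10998 in the background-subtracted signal. From 12 h to 1 day it changed for 56 and 2648 probes, from 1 to 3 days for 1591 and 6441, from 3 to 5 days for 1308 and 5116, and from 5 to 8 days for 713 and 5457. These differences between times are the reason the probes are listed here. Groups of 3 arrays were not tested for single outlying arrays.

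Splits of the same arrays show how often other groupings give as many calls. At each time 3 arrays against 3 make 10 splits, too few for a share under 0.05, and 1 of 10 splits, the real one, gave the real count. In the processed signal the real counts at 12 h and 1, 3, 5 and 8 days were 20, 668, 2864, 1674 and 1826, and the highest of the other splits gave 0, 2, 488, 131 and 1. In the background-subtracted signal they were 2180, 6038, 6121, 5523 and 7458, and the highest others 2, 0, 277, 17 and 8. For the mean over times, a response at any time, a response that differs between times and a change in mock roots, 100 splits included the real one. Only the real one gave the real count. All splits ignored slide and array row, which partly follow the groups, so they leave slide and row open. A true difference between groups also widens the spread within other splits, which lowers their counts. The real counts were 2174, 4227, 3292 and 7062 against at most 413, 491, 280 and 3289 in other splits, and 6730, 11672, 10998 and 12199 against at most 2157, 3454, 2463 and 8375 in the background-subtracted signal.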

How the results depend on the processing

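The background-subtracted signal, the array row as a block, the array subsets and the averaging of linked probes were chosen after the data were examined, and the rest before. No named probe changed direction under any alternative in the comparison it was named for. At other times some small differences that did not pass the test did, such as those of xigua01167, xigua12204 and xigua02709 at 3 days in the background-subtracted signal. Of 628 values of named probes under alternatives, 579 kept their side of the threshold and 49 lost it, all 49 at 12 h or 1 day. The cause of each change of count below was not tested unless stated. Counts are given for 12 h, 1, 3, 5 and 8 days in that order, then the mean effect, a response at any time, a response that differs between times and the change in mock roots.

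Counts from the processed signal were 20, 668, 2864, 1674 and 1826, then 2174, 4227, 3292 and 7062. Normexp gave 1961, 5362, 5575, 5182 and 7045, then 6357, 11093, 10411 and 12081. For named probes near background normexp gave the smallest differences, below the printed lower bound for each of the 5 probes that had one where it was named, so those bounds hold for the processed signal only. Like the background-subtracted signal, normexp starts from values without the software's surface. That signal gave 2180, 6038, 6121, 5523 and 7458, then 6730, 11672, 10998 and 12199, and between neighbouring times 2648, 6441, 5116 and 5457. Array weights gave 6983, 6950, 4402, 3749 and 8616, then 6426, 12606, 11955 and 12859. The 20 arrays without a multiplicative correction gave 453, 5201, 4446 and 4982 at 12 h, 1, 5 and 8 days, then 4763, 9437, 8206 and 10897, with 1 inoculated array left at 12 h and 8 days and 1 mock array at 3 days. Without the 3 arrays farthest from their groups the counts were 727, 3092, 1650, 2624 and 5057, then 3685, 7437 and 6408. The slide as a fixed block gave 47, 151 and 451 at 12 h, 1 and 3 days and 2009 for a response that differs between times, and as a random block (estimated correlation within slides 0.144) 1647 at 3 days. The array row as a block gave 0 at 12 h, 1162 at 3 days and 1146 at 8 days. Arrays of 1 slide and row gave 68, 1217 and 1395 at 12 h, 1 and 3 days, each with a single array in 1 arm. Single arrays were assumed to vary like the other groups. Each time fitted on its own gave 4293, 177, 1037 and 3106 at 1, 3, 5 and 8 days. A 2-fold minimum, which can only remove calls, left 444, 1176, 1021 and 981 at 1, 3, 5 and 8 days and 167 for the mean effect. Linked probes averaged gave 94 at 12 h. Probes called in the same direction at 2 or more times, including those with an opposite call at another time, numbered 1251, 682 with a 2-fold minimum and 6957 in the background-subtracted signal, and 1124, 634 and 3944 without an opposite call. Centring on the median, quantile normalization, the authors' value table, the filters on dim probes and the intensity trend with robust variance moved no total by over 1.5 times. The authors' value table holds the processed signal itself, so it could not move a total. Centring on the median did move splits, at 3 days from 1600 higher and 1264 lower to 900 and 1988.

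Same-numbered arrays of inoculated and mock roots had deviations that correlated from -0.34 upward in the processed signal. The highest values were 0.41 and 0.56, for numbers 1 and 2 at 12 h. In the background-subtracted signal they ran from -0.34 to 0.14. With deviations from means of 3 arrays, these values do not settle whether a number marks an experiment. The replicate block gave 6 calls at 12 h and changed no other count of a response to inoculation by over 1.5 times. For the change in mock roots it gave 2269. Its coding made that test compare levels at replicate number 1 instead of group means, so this count is not comparable with the main one. Within a time, inoculated arrays correlated best with the mock array of their own number in 2, 1, 1, 0 and 1 of 3 cases.

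In the background-subtracted signal a 2-fold minimum left 96, 594, 922, 962 and 1063 at the 5 times and 155 for the mean effect. Linked probes averaged, with fewer values tested, gave 1406, 3552, 3602, 3263 and 4307, then 3934, 6664, 6323 and 6933. The array row as a block gave 1173 at 12 h, the slide as a block 3757 at 3 days, and each time on its own 2910 at 3 days. The arrays without a multiplicative correction gave 459 at 12 h and 3280 at 3 days, with fewer arrays, and arrays of 1 slide and row 286, 3367 and 3370 at 12 h, 3 and 5 days. Centring on the median turned its split from 911 higher and 1269 lower to 1574 and 735 at 12 h, from 1960 and 4078 to 2806 and 2315 at 1 day, from 3334 and 2787 to 2141 and 3643 at 3 days, from 2594 and 2929 to 2965 and 2619 at 5 days, and from 4216 and 3242 to 3492 and 3969 at 8 days, so which direction holds the majority of calls depends on the centring. Quantile normalization gave 3679 and 3871 at 8 days.

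Without single arrays, counts from the processed signal ran from 0 to 19 at 12 h, 235 to 431 at 1 day, 1728 to 4761 at 3 days, 1022 to 1807 at 5 days and 1072 to 1465 at 8 days. They ran from 1878 to 3465 for the mean effect, 3615 to 6273 at any time, 2763 to 5106 for a response that differs and 6181 to 9261 in mock roots. In the background-subtracted signal they ran from 1422 to 1707, 4702 to 5564, 5219 to 5880, 4694 to 4967 and 6502 to 6940 at the 5 times, and only the 12 h count without mock replicate 3 (1422) lay over 1.5 times below the full one. Alternatives for gene lists were not run, because no gene names were used. With the 741 dim probes included, counts were 20, 638, 2780, 1593 and 1778 at the 5 times.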

Other observations

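All tests below except that of the place of linked probes on the array were chosen after their results were seen. Among probes that differed at least 2-fold, being lower in inoculated roots at 3 days alone was the most frequent pattern over time. In the background-subtracted signal 433 probes were lower at 3 days only, 335 were higher at 8 days only, 255 were lower at 5 days only and 131 were higher at 5 and 8 days. In the processed signal these were 499, 299, 277 and 126. "Only" means that no other time passed both the test and the 2-fold minimum. By the test alone, without the 2-fold minimum, the most frequent pattern was higher at 8 days only (596) in the background-subtracted signal and higher at 3 days only (1042) in the processed signal.

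Probes whose levels differed at 3 days were often probes that change with time in mock roots. Of the 680 probes at least 2-fold lower in inoculated roots at 3 days in the background-subtracted signal, 324 (47.6%) rose at least 2-fold in mock roots from 1 to 5 days and 1 fell, against 6.73% and 3.29% of all 13973 probes. Of the 242 higher probes, 117 (48.3%) fell in mock roots over that interval. In the processed signal 293 of 725 lower probes (40.4%) rose and 135 of 451 higher probes (29.9%) fell. At 5 days in the background-subtracted signal, 112 of 373 higher probes (30%) fell in mock roots from 3 to 8 days, and 116 of 589 lower probes (19.7%) rose. Among all probes 4.67% fell and 4.52% rose over that interval. In the processed signal these were 100 of 419 (23.9%) and 126 of 602 (20.9%), against 7.26% and 7.29% of all probes. At 1 day in the background-subtracted signal, of 290 higher probes 22.8% fell and 18.3% rose in mock roots from 12 h to 3 days. Of 304 lower probes 27.3% rose and 6.25% fell, against 3.53% of all probes that fell and 6.79% that rose. No array is shared between these differences and these intervals, but slides are. The inoculated arrays of 3 days and the mock arrays of 1 day lay on slide 2. Mock replicates 2 and 3 of 3 days and the mock arrays of 5 days lay on slide 3. A difference between slides 2 and 3 could therefore enter both.

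Each array was therefore placed on the line from the earlier to the later mock mean around its time, with 0 at the earlier mean and 1 at the later. At 3 days inoculated arrays lay at 0.15 ± 0.10 and mock arrays at 0.60 ± 0.05 (SD, n = 3), a difference of -0.44 in the background-subtracted signal and -0.44 in the processed signal, so that the software's surface does not account for it. On the 1 slide and array row that held both, the only mock array lay 0.355 above the highest of the 3 inoculated arrays, and a single array excludes neither slide nor array row. At 1 day the only inoculated array on the slide and row of the mock arrays (0.317) lay among them (0.286 to 0.344), and at 5 days the only one (0.0911) lay below them (0.352 to 0.411). Over whole groups the differences at 1 and 5 days were -0.06 (exact p = 0.3) and -0.25 (exact p = 0.1), and -0.05 and -0.15 in the processed signal. At 3 days the exact p was 0.1 as well, the smallest that 20 splits of the labels allow. With the lines held fixed and labels permuted only within a time, slide and array row, the sum over 1, 3 and 5 days had a two-sided p of 0.0469 in both signals, from 64 permutations that cannot give a p under 0.0156. This permutation holds slide and array row fixed, but at each time it rests on a single array of 1 arm. It does not hold the column of an array on its slide fixed. In each of these slides and rows the inoculated arrays lay in lower-numbered columns than the mock arrays. Slide and array row stay open for the differences over whole groups. Array column, a delay through inoculation and a different growth state of the inoculated plants for another reason stay open as well.

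Most of the spread within groups came from a few arrays: mock replicates 2 and 3 at 3 days and inoculated replicate 1 at 5 days held 53.9% of the within-group squares of the processed signal. Using the signal before the multiplicative correction removed 72.7% of all within-group squares, and those 3 arrays then held 13.7%. Position on the array explained at most 6.51% of their deviation before the correction, which argues against a gradient of hybridisation. The correlation over probes of the 3-day difference between linked probes (described next) differed by -0.26 between the processed and the background-subtracted signal (lower in the processed one), which argues against a gradient rightly removed, and the farthest of the 3 arrays deviated 1.5 times as much as the median array before the correction, which argues against other RNA. The surface fitted by the software may therefore be the source of this spread, and no biological explanation was tested.

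Probes whose numbers differ by 6572 had nearly the same profile over the 30 arrays in the background-subtracted signal. The median correlation at that distance was 0.915 over all pairs, and the highest at any other distance was 0.0628. From number 1571 on, 6215 measured pairs had a median of 0.944, and 0.603 in the processed signal with its surfaces, so the 14714 probes may stand for 8142 targets, with 1570 measured by a single probe. Linked probes within 10 rows and columns of each other correlated higher than those over 50 rows apart by only 0.0378, which argues against a shared place on the array. Most named probes are such pairs. These are xigua03927 with xigua10499, xigua02709 with xigua09281, xigua05727 with xigua12299, xigua05675 with xigua12247, xigua05632 with xigua12204 and xigua07126 with xigua13698. The 2 probes of such a pair may be no separate examples, and a count of probes can hold 1 target under 2 identifiers.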
